A study of Mus musculus with 7 samples.

How the data were processed

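RNA was measured in 7 libraries of mouse granulocytes, the blood and tissue leukocyte class that holds neutrophils, eosinophils and basophils. Per the labels' protocols, RNA was purified on columns and treated with DNase, and libraries were made from polyA RNA with a QuantSeq kit, which reads tags near the 3′ end of transcripts. The libraries came from animals or cells that were wild type (n = 4) or knockout (n = 3) for Alox15, and all carried the label untreated. The tissue the cells were taken from, their sorting and the deleted part of Alox15 were not given in the sources used here. Nothing in the labels says whether the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

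The authors deposited 1 table of counts per Ensembl mouse gene for all 7 libraries. Per the submitters' processing notes, RSEM 1.2.3, DESeq2 and the mm10 genome were used, with no role given for each. RSEM gives expected counts, and the values the authors deposited are whole numbers, so they may be rounded estimates; rounding here changed nothing. The annotation release, the strand setting and the treatment of reads that match several genes were not given in the sources used here, so values of pseudogenes, paralogs and overlapping genes are uncertain. The labels name no molecular identifiers, and PCR reads without them are not independent molecules, so intervals and upper limits cover counting error only.

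The table held 51789 genes, of which 51596 matched a symbol in the reference and 193 did not. Coordinates and gene types came from GENCODE M21, whose genome is GRCm38, the same build as mm10, and are 1-based. Total counts ran from 3228292 to 5657192 per library, so 3 counts, the upper limit that a count of 0 allows, stood for 0.929 to 0.530 CPM in single libraries. The 12506 genes kept for testing held 99.6% of the counts.

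Groups came from the labels. The main comparison, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. The comparison was knockout against wild type with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group design, TMM scaling, a robust quasi-likelihood F test and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. CPM values are scaled by the TMM library sizes. Log2 CPM values carry a prior count of 2. Error on a log2 fold change is its standard error from the F test.

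Gene groups were 28 lists: neutrophil maturation (granule genes, mature neutrophil genes, phagocyte NADPH oxidase), cell states (proliferation, interferon-stimulated genes, NF-kB targets, stress responses, immediate early genes), metabolism (ferroptosis, eicosanoids, glycolysis, oxidative phosphorylation, cholesterol, lipid uptake), myeloid suppression, MHC class II, markers of other cell types, genes flanking Alox15, sex-linked transcripts and mitochondrially encoded transcripts. Lists with 3 or more tested members were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The mitochondrial list had no member in the table and the basophil and mast cell list had 2 tested members, so neither was tested. A list score is the mean log2 CPM of the tested members. Scores were compared between groups by exact two-sided permutation of the 35 ways to choose 3 of the 7 libraries, where the smallest possible p is 0.0286. Correlations over the 7 libraries used all 5040 orders.

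Named genes followed a rule. They were Alox15, up to 12 genes per direction that have a gene symbol other than a clone or predicted-gene name or a numbered pseudogene, past the threshold with a mean log2 CPM of at least 3 and no overlap between groups, and up to 4 members of each list with the smallest unadjusted p. Since no gene passed, the rule named the 5 genes per direction with the smallest unadjusted p at the same level and with the same kind of name.

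Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile factors, no filter, a filter of 5 CPM in 3 libraries, a fold threshold, leaving out each library, the replicate number as a block, and the stem of the sample description as a covariate. Chosen after seeing the data were the mature neutrophil score and a surrogate variable (sva 3.50.0) as covariates, the stem covariate for the lists, and leaving out wild type 2 and knockout 3 together.

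The test was checked on simulated counts for 12506 genes with the means, library sizes and dispersions of these libraries and 200 changed genes, in 3 runs for the comparison of knockout with wild type. It recovered 1.33% of genes changed 2-fold, 39.3% of those changed 4-fold, 80.7% of those changed 8-fold and 91.3% of those changed 16-fold, with 7 false calls per run on average. The changed genes all had a mean above 8 CPM, so recovery at lower levels was not checked. With the score as a covariate and a lower dispersion, 940 of 1000 genes tied to the score were recovered among 12343 genes in 1 run, with 43 false calls. Camera, also at the lower dispersion and in 1 run, recovered the 1 list raised 4-fold, with 1 false call among 26 lists. Genes were drawn independently of each other there. The run therefore does not check camera on lists whose members vary together. All 21 pairs of libraries, within and between groups, differed far beyond counting noise (chi-square per degree of freedom 22.6 to 150.3), so no library was a copy of another.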

Results

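Gene expression was profiled in mouse granulocytes that were wild type or knockout for Alox15, by 3′ tag sequencing of polyA RNA. Alox15 encodes arachidonate 15-lipoxygenase, an enzyme that adds oxygen to polyunsaturated fatty acids. The title of the series concerns ferroptosis, a form of cell death driven by lipid peroxidation, in neutrophils of tumours. The 4 wild-type libraries held 3606843, 5657192, 4981010 and 3907353 counts and the 3 knockout libraries 5250060, 3228292 and 5348256. Between 14657 and 15560 genes had at least 1 count in a library.

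Alox15 (ENSMUSG00000018924, protein-coding, minus strand of chromosome 11, 70344152 to 70352031, GRCm38) was not detected in any wild-type library. Its count was 0 of 18152398 over the 4 libraries, which allows up to 0.165 CPM by the limit of 3 counts and up to 0.203 CPM by an exact 95% interval. In the knockouts, 1 count was found in replicate 1 and 0 in replicates 2 and 3, or 0.0723 CPM over the group with an exact 95% interval of 0.00183 to 0.403 CPM. No fold change is given, since both groups lay at or under the floor of 3 counts. Because wild type was also at 0, and the tags may lie outside the deleted part, Alox15 does not check the genotype labels.

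Sex-linked transcripts divided the knockout libraries. Xist, the RNA that coats the inactive X chromosome, stood at 382 CPM in knockout 2 and 102 CPM in knockout 3, against 1.75 CPM in knockout 1 and 0.896 to 6.11 CPM in the 4 wild-type libraries. The Y-linked helicase gene Ddx3y showed the opposite, with 119 CPM in knockout 1, 19.3 to 108 CPM in wild type and 0.306 and 0.195 CPM in knockouts 2 and 3. Eif2s3y, Kdm5d and Uty had 0 counts in knockouts 2 and 3, and Uty also had 0 in wild type 4. By these values knockouts 2 and 3 had the sex-linked transcripts of females, and knockout 1 and the 4 wild-type libraries those of males. Knockouts 2 and 3 were also the libraries whose descriptions had another stem than the remaining 5. Sex, description stem and part of the genotype contrast therefore ran together and cannot be told apart here.

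**Figure D1:**
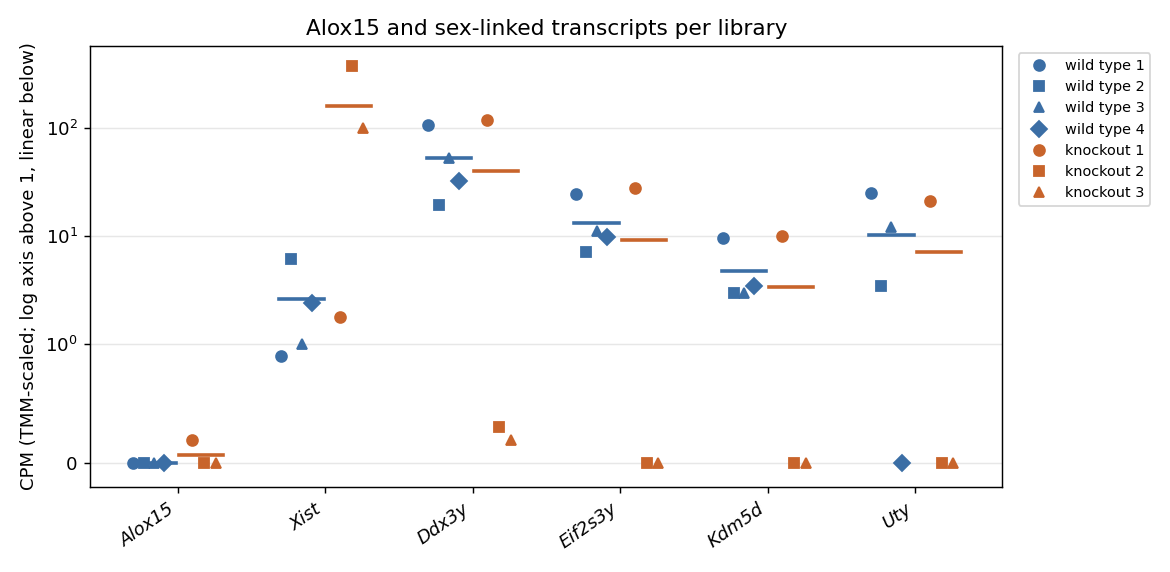
Alox15 and 5 sex-linked transcripts per library, as TMM-scaled CPM (axis logarithmic above 1 and linear below); points are single libraries and horizontal lines group means, wild type (n = 4) in blue and knockout (n = 3) in orange. Xist is high in knockout 2 (382 CPM) and knockout 3 (102 CPM), where Ddx3y stands at 0.306 and 0.195 CPM.

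The comparison of knockout with wild type asked which transcripts differ in granulocytes that lack Alox15. No gene passed the test against the spread between libraries. Neutrophil transcripts were present in all libraries and varied widely within each genotype: S100a8 ran from 970 to 10487 CPM in wild type and from 986 to 7695 CPM in knockout. The T cell receptor part Cd3d exceeded the mature neutrophil gene Cxcr2 in knockout 3 (441 against 37.8 CPM) and wild type 2 (202 against 71.7 CPM). Cxcr2 was the higher in the other libraries, and S100a8 exceeded Cd3d in all. The comparison thus concerns libraries labelled granulocytes that also held T lineage transcripts. Genes of ferroptosis, eicosanoid synthesis and myeloid suppression did not pass in either direction. Arg1, arginase 1 of suppressive myeloid cells, averaged 60.6 ± 36.9 CPM (SD, n = 3) in knockout and 18.3 ± 5.15 CPM (SD, n = 4) in wild type, with an unadjusted p of 0.00583 in edgeR that did not survive adjustment (adjusted p = 0.99995).

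Of 12506 genes tested with edgeR, 0 were higher and 0 were lower in knockout. At an unadjusted p under 0.05 there were 154 genes, 56 higher and 98 lower, where 625.3 would be expected by chance. The 2 groups did not overlap for 392 genes, or 3.13%, against 5.71% by chance. DESeq2 called 1 gene and had 354 genes at an unadjusted p under 0.05. Limma-voom called 0 and had 524. The gene DESeq2 called was Impdh2-ps, a processed pseudogene on chromosome 8 (log2 fold change -4.94, DESeq2 adjusted p = 0.00566, against 0.354 to 1 in the other settings), with 0, 0 and 7 counts in the knockouts and 30, 67, 124 and 66 in wild type. Its reads may be shared with Impdh2. The biological coefficient of variation was 0.563.

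The genes with the smallest unadjusted p that the naming rule allows, which leaves out predicted and clone names and low levels, are given as values, since none passed in edgeR. On the knockout side, besides Xist, they were Ly75, the endocytic receptor DEC-205, with a log2 fold change of 1.61 ± 0.45 (SE), Arg1 with 1.73 ± 0.49, Slc1a4, a neutral amino acid transporter, with 1.12 ± 0.33, and Uchl1, a ubiquitin hydrolase, with 1.00 ± 0.31. Slc1a4 stood at 28.2 to 37.6 CPM in the knockouts and 12.4 to 17.5 CPM in wild type. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) reached 92.7 and 68.9 CPM in knockouts 1 and 2, but 20.3 CPM in knockout 3, inside the wild-type range of 10.96 to 22.6 CPM. On the wild-type side were the pseudogene Impdh2-ps, with the smallest p of all (0.00136) and a log2 fold change of -4.90 ± 1.10, then Gnb2, a G protein subunit, with -1.15 ± 0.31, Rbm4b, an RNA-binding protein, with -1.34 ± 0.37, Dnajc24 with -2.59 ± 0.72, and Uckl1, a uridine-cytidine kinase, with -1.24 ± 0.38. Gnb2 averaged 52.2 ± 11.9 CPM (SD, n = 3) in knockout and 116 ± 28.9 CPM (SD, n = 4) in wild type. For Impdh2-ps only knockout 3 had counts among the knockouts, and without it the fitted value was -9.13, which depends on the prior count. The smallest adjusted p from edgeR over all genes was 0.99995.

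**Figure D2:**
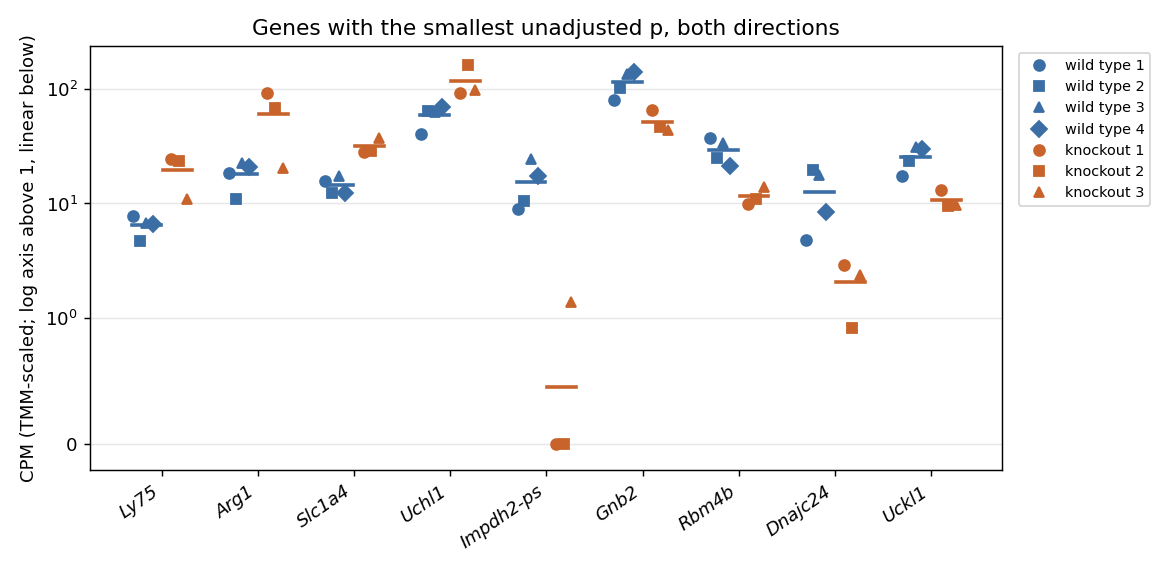
TMM-scaled CPM per library (axis logarithmic above 1 and linear below) of the 9 autosomal genes with the smallest unadjusted p in both directions among those the naming rule allows; points are single libraries and horizontal lines group means, wild type (n = 4) in blue and knockout (n = 3) in orange. Arg1 in knockout 3 (20.3 CPM) lies inside the wild-type values, and no gene shown passed adjustment in edgeR.

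Of the 32 tested members of the ferroptosis list, 13 were nominally higher and 19 lower, and 0 passed over all genes or adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.929). Slc7a11, the cystine carrier that feeds glutathione synthesis, stood at 175 ± 99.6 CPM (SD, n = 4) in wild type and 146 ± 117 CPM (SD, n = 3) in knockout. Gpx4, the peroxidase that removes lipid peroxides, stood at 27.9 ± 20.3 and 36.2 ± 12.1 CPM. Acsl4, which loads polyunsaturated fatty acids onto coenzyme A, stood at 128 ± 34.99 and 126 ± 34.5 CPM. The members with the smallest unadjusted p were Steap3, Gclm, Gss and Keap1, with log2 fold changes of -0.93 ± 0.76, -0.40 ± 0.34, 0.86 ± 0.82 and 0.18 ± 0.24 (SE). The value of Gss was 1.54 without wild type 3.

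The eicosanoid list had 17 tested members, 6 nominally higher and 11 lower, and 0 passed over all genes or adjusted over the list alone (median -0.15, camera adjusted p = 0.221). Alox5, the 5-lipoxygenase of leukotriene synthesis, stood at 30.1 ± 28.8 CPM (SD, n = 4) in wild type and 18.9 ± 16.1 CPM (SD, n = 3) in knockout, and Ptgs2, cyclooxygenase 2, at 423 ± 291 and 381 ± 352 CPM. Of the other lipoxygenases, Alox12b and Alox12e had 0 counts in all 7 libraries and Alox12 had 0 in all but wild type 2. In the list of suppressive myeloid genes, 9 of 22 tested members were nominally higher and 13 lower, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.929). Beside Arg1, Tnfrsf10b, the TRAIL receptor, had a log2 fold change of -1.28 ± 0.65 (SE) and Xbp1 one of -0.97 ± 0.53. Spp1 had 1.11 ± 0.62, which turned to -0.048 without knockout 1, the library with 383 CPM.

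Among the 26 lists tested, camera with the preset correlation called 5, each toward higher values in knockout, although 0 of their members passed over all genes or adjusted over the list alone. None of the 5 held with an estimated correlation (adjusted p = 0.979 for granule genes and 0.891 for the other lists), and fry gave an adjusted p of 0.990 for each. For MHC class II genes, which present antigen to CD4 T cells, 11 of 11 tested members were nominally higher (median log2 fold change 0.78, camera adjusted p = 0.00106). H2-Aa stood at 439 ± 208 CPM (SD, n = 3) in knockout and 261 ± 144 CPM (SD, n = 4) in wild type, and the costimulatory gene Cd86 reached 50.7 CPM in knockout 1 but 6.43 and 2.73 CPM in knockouts 2 and 3. Without knockout 1 the MHC class II median was -0.23 and the camera adjusted p 0.914; without wild type 2 the adjusted p was 0.108.

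Of 17 monocyte and macrophage markers, 16 were nominally higher (median 0.81, camera adjusted p = 0.000773, 0.891 with an estimated correlation). The complement gene C1qb stood at 161, 66.5 and 31.5 CPM in the 3 knockouts and at 15.5 to 52.2 CPM in wild type, and F13a1, the coagulation factor XIII subunit, at 168, 56.1 and 19.7 CPM and 9.24 to 55.9 CPM. This call was lost without knockout 1 (median 0.059, adjusted p = 0.973) and without wild type 2 (adjusted p = 0.0712). Of 11 B cell markers, 9 were nominally higher (median 0.57, camera adjusted p = 0.00322, 0.891 with an estimated correlation), lost without knockout 1 (adjusted p = 0.214) or wild type 1 (adjusted p = 0.730). Ms4a1, which encodes CD20, ran from 0 to 11.4 CPM in wild type and from 5.45 to 23.9 CPM in knockout.

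Of 14 tested members of the granule list, 12 were nominally higher (median 0.47, camera adjusted p = 0.0305, 0.979 with an estimated correlation). The list holds granule products of neutrophil precursors but also Ly6g and the NADPH oxidase gene Cybb. Its score went with the mature neutrophil score over the 7 libraries (r = 0.932), so the list does not separate precursors from mature cells. Chil3 stood at 46.2 ± 41.8 CPM (SD, n = 3) in knockout and 12.6 ± 19.0 CPM (SD, n = 4) in wild type, where wild type 1 held 40.9 CPM and the others 1.10 to 4.77 CPM. Its log2 fold change was 1.90 ± 1.12 (SE), 3.85 without wild type 1 and 0.87 without knockout 2. The granule call was lost without wild type 2 (adjusted p = 0.650), wild type 3 (0.0814), knockout 1 (0.580) or knockout 2 (0.479). Of 7 tested tumour and stromal markers, 6 were nominally higher (median 0.65, camera adjusted p = 0.000773, 0.891 with an estimated correlation). The matrix protein gene Sparc ran from 28.8 to 37.7 CPM in knockout and from 8.54 to 27.9 CPM in wild type, and the endothelial and leukocyte adhesion gene Pecam1 from 31.5 to 39.7 CPM and from 17.0 to 27.3 CPM. The stromal call was lost without knockout 3 (adjusted p = 0.0600). The epithelial marker Epcam had 0 counts in all 7 libraries.

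The other 21 lists were not called (camera adjusted p 0.134 to 0.935), and 0 of their members passed over all genes. Adjusted over the list alone, Xist passed among the sex-linked transcripts (edgeR adjusted p = 0.0121, log2 fold change 5.88 ± 1.40, SE, high in 2 of 3 knockouts, 4.26 without knockout 2 and 6.81 without wild type 2) and no gene passed in the other 20 lists. Nominally higher members numbered 11 of 28 mature neutrophil genes, 10 of 28 proliferation genes, 13 of 33 interferon-stimulated genes, 8 of 29 NF-kB targets and 4 of 9 NADPH oxidase genes. They numbered 12 of 25 stress response genes, 13 of 23 glycolysis and hypoxia genes, 16 of 30 oxidative phosphorylation genes, 17 of 25 cholesterol and fatty acid genes, 10 of 19 lipid uptake genes and 9 of 23 immediate early and heat shock genes. Of the 44 genes flanking Alox15 on chromosome 11, 24 were nominally higher, and camera gave an adjusted p of 0.929. For markers of other cells, nominally higher members numbered 1 of 3 for eosinophils, 2 of 4 for dendritic cells, 8 of 12 for T and NK cells, 5 of 5 for erythroid cells and 2 of 3 for platelets. Of the basophil and mast cell list, Cpa3 stood at 12.9 ± 9.48 CPM (SD, n = 4) in wild type and 10.6 ± 4.51 CPM (SD, n = 3) in knockout. The median, the mean and the camera direction differed in sign for 9 lists, none of them called.

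Several of these uncalled lists were called by camera with 1 library left out, some in opposite directions. Mature neutrophil genes were lower in knockout without wild type 2 (adjusted p = 1.26e-05), knockout 1 (0.000317) or knockout 2 (0.0140), and higher without knockout 3 (3.97e-06). NF-kB targets were lower without wild type 2 (adjusted p = 5.35e-05), knockout 1 (1.77e-05) or knockout 2 (0.0479), and higher without knockout 3 (0.000873). Interferon-stimulated genes were lower without wild type 2 (adjusted p = 0.000116) or knockout 1 (0.00265) and higher without knockout 3 (0.00406), and suppressive myeloid genes were lower without knockout 1 (0.0341) and higher without knockout 3 (0.00648). Oxidative phosphorylation genes turned the other way, higher without knockout 2 (adjusted p = 0.0298) and lower without knockout 3 (0.000428), as did cholesterol and fatty acid genes (0.0298 and 0.000309). Called in 1 direction only were eicosanoid genes, lower without knockout 1 (adjusted p = 0.0341), and immediate early and heat shock genes, lower without wild type 2 (0.00113) or knockout 1 (0.00296). Proliferation genes were lower without wild type 1 (adjusted p = 0.000105) or knockout 3 (0.00406), and sex-linked transcripts were lower without wild type 4 (0.0481) or knockout 1 (8.24e-05). Lipid uptake genes were higher without wild type 1 (adjusted p = 0.0440) or knockout 3 (0.000414), erythroid markers without wild type 3 (0.0365) or knockout 2 (0.0298), and T and NK cell markers without knockout 1 (0.0341). Ferroptosis genes were not called in any of the 7 fits that left out 1 library. These fits used the preset correlation alone.

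**Figure D3:**
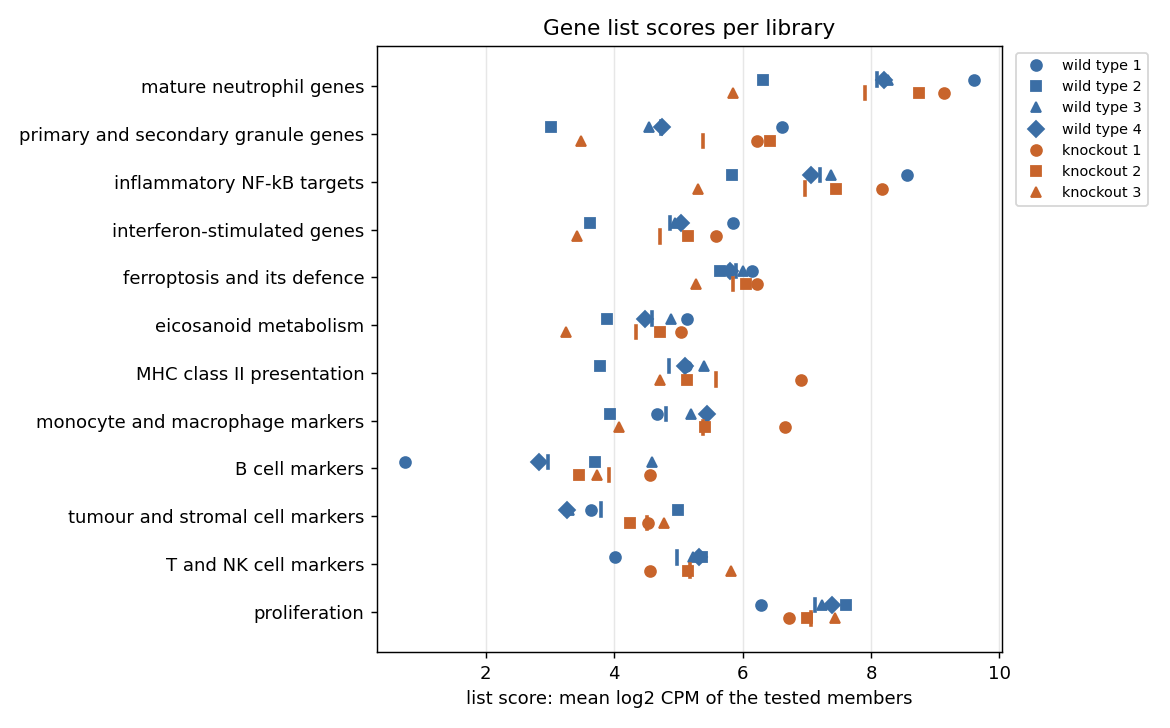
Score of 12 gene lists in each library (x axis: mean log2 CPM of the tested members); points are single libraries and vertical bars group means, wild type (n = 4) in blue and knockout (n = 3) in orange. Mature neutrophil scores run from 5.85 to 9.60, and wild type 2 (6.32) and knockout 3 (5.85) lie lowest.

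Mature neutrophil transcripts differed more within genotypes than between them. The mature neutrophil score, over genes such as Cxcr2, Mmp9 and Retnlg, was 8.10 ± 1.35 (SD, n = 4) in wild type and 7.91 ± 1.80 (SD, n = 3) in knockout (exact two-sided permutation p = 0.886). It spanned 13.5-fold over the 7 libraries, with wild type 2 at 6.32 and knockout 3 at 5.85 and the others between 8.20 and 9.60. S100a8 and S100a9 together took 2.05% of counts in wild type 1 (Wilson 95% interval 2.04 to 2.06%) and 0.165% in knockout 3 (0.162 to 0.169%). Ribosomal protein genes took 7.76% (7.74 to 7.79%) and 22.2% (22.1 to 22.2%) in the same libraries. The first principal component held 41.3% of the variance and placed wild type 2 (66.0) and knockout 3 (90.7) at one end and wild type 1 (-79.2) and knockout 1 (-60.7) at the other. Log2 CPM correlations across genes, which are not independent replicates, had a median of 0.861 for pairs of libraries within a group and 0.867 for pairs between groups.

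Scores of most other lists went with the mature neutrophil score over the 7 libraries. In a family of 25 correlations, each with members of the mature neutrophil list left out of the other list, 16 had an exact adjusted p under 0.05 for Pearson's r, 12 positive and 4 negative, and 14 of them also for Spearman's rho. The relation was thus not particular to the lists named next. Among them, NF-kB targets gave r = 0.989 (exact permutation p = 0.000198, adjusted p = 0.00165; Spearman rho = 1, exact p = 0.000397, where the smallest p that 5040 orders give is 0.000198). Interferon-stimulated genes gave r = 0.996 (exact adjusted p = 0.00248; rho = 0.964, exact adjusted p = 0.00868), suppressive myeloid genes r = 0.991 (exact adjusted p = 0.00165; rho = 1, exact adjusted p = 0.00248) and ferroptosis genes r = 0.944 (exact adjusted p = 0.00496; rho = 0.964, exact adjusted p = 0.00868). Without wild type 2 and knockout 3, the libraries farthest from the median, these r were 0.963, 0.973, 0.945 and 0.803. Granule genes, a list called by camera, gave r = 0.932 (exact adjusted p = 0.00827; rho = 0.893, exact adjusted p = 0.0237) and 0.882 without the same libraries. The stress response and lipid uptake lists passed for r (0.775 and 0.879) but not for rho, and their r fell to 0.342 and 0.345 without those libraries, so these relations rest on them. T and NK cell markers ran the other way, with r = -0.837 (exact permutation p = 0.0226, adjusted p = 0.0435; rho = -1, exact adjusted p = 0.00248) and -0.962 without the same libraries. Proliferation genes gave r = -0.833 (exact adjusted p = 0.0435; rho = -0.964, exact adjusted p = 0.00868) and -0.990. Monocyte and macrophage markers gave r = 0.704 (exact adjusted p = 0.114; rho = 0.5, exact adjusted p = 0.333), and B cell markers r = -0.352 (exact adjusted p = 0.492; rho = -0.250, exact adjusted p = 0.647), neither past the threshold. The description stems hold 5 and 2 libraries, fewer than the 6 set as the minimum for reporting a correlation within a batch, and none was computed there.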

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

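The tests of the spread in neutrophil transcripts were chosen after the result was seen. Of 69 outlier checks on the 4 wild-type libraries, 4 found a library far from the rest, where chance gives about 1 in 20 (3.45 expected). The T and NK cell score of wild type 1 was 4.01, with the other libraries at 5.23 to 5.36. Fn1, which encodes fibronectin, stood at 6.87 CPM in wild type 1 and at 24.9 to 31.0 CPM in the others. Gclm, a subunit of the enzyme that starts glutathione synthesis, stood at 27.4 CPM in wild type 3 and at 43.2 to 46.3 CPM in the others. Cald1, a contractile and stromal gene, stood at 4.23 CPM in wild type 2 and at 1.39 to 1.59 CPM in the others.

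The low T and NK score of wild type 1 goes with the highest mature neutrophil score (9.60). Over all 7 libraries mature neutrophil transcripts spanned 13.5-fold, from knockout 3 to wild type 1. Within genotypes the score ran from 6.32 to 9.60 in wild type and from 5.85 to 9.14 in knockout. Sequencing depth as the source is argued against by knockouts 1 and 3, whose totals differed 1.02-fold while their scores differed by 3.29 on the log2 scale. A lower share of neutrophils with every other cell type raised alike is argued against by T and NK minus monocyte and macrophage scores, which followed the neutrophil score (r = -0.895, exact permutation p = 0.00992; rho = -0.929, exact p = 0.00675; r = -0.585 without the 2 libraries farthest from the median). A varying share of cells with T lineage and cycling transcripts stays open: the T and NK score had r = -0.837 with the neutrophil score, and this may reflect carry-over of such cells or a difference in the sort, which was not given in the sources used here. No biological explanation was tested, since the design names only genotype, and the score did not differ between genotypes beyond the spread (exact permutation p = 0.886).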

How the results depend on the processing

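The count of 0 changed genes held with RLE and upper-quartile factors, without and with a stricter filter, with limma-voom, a fold threshold and each library left out, and with the covariates and the pair of left-out libraries chosen after seeing the data; DESeq2 called 1. The stem covariate also gave 0 genes, but with it only knockout 1 carries the genotype contrast and is assumed to vary like the other libraries, so it says nothing on stability. Of the named genes, 37 were recomputed: those with the smallest p over all genes and those of 7 lists (granule, ferroptosis, eicosanoid, suppressive, MHC class II, monocyte and macrophage, stromal). None passed in any setting but Impdh2-ps with DESeq2 (-4.94). Of 764 alternative values of their fold changes and of 5 list medians, 739 kept direction and side of the threshold, 1 gained and 20 list values lost the call and 4 reversed. Of the 739, 690 are fold changes of single genes that did not pass the threshold in that setting or in the main fit. Only their direction was therefore at stake, and their size could differ (Chil3 0.87 to 3.85 over left-out libraries). Reversed were Xist with the stem covariate (-0.64, where knockouts 2 and 3 are alone in their stem), and, without knockout 1, Spp1 (-0.048 to 1.54 over left-out libraries), Cd86 (-0.38 to 2.23) and the MHC class II median (-0.23 to 1.08). The 5 list calls became 0 with an estimated correlation, 0 with fry, 11 with the stem covariate (knockout 1 alone against wild type) and 9 without wild type 2 and knockout 3 (both chosen after seeing the data), and 5 to 12 with single libraries left out (9 without knockout 1, 9 without knockout 2 and 12 without knockout 3), where lists such as mature neutrophil genes and NF-kB targets turned direction; the cause was not tested. Replicate numbers are shared across genotypes. Deviations of same-numbered libraries correlated at 0.349, -0.225 and -0.184, and among the knockouts only knockout 1 correlated best with its own number. The highest correlation (0.470) was that of wild type 2 with knockout 3, the libraries with the lowest mature neutrophil scores. These values therefore show no pairing by number but cannot exclude it. With the replicate block 0 genes and 7 lists were called. Fits with the block or the stem tested 14901 genes and those with the neutrophil score (7 lists) or the surrogate variable 13454, since the filter follows the design. All 5 lists of the main fit stayed called with the neutrophil score, at camera adjusted p from 6.03e-08 (granule genes) to 0.0112 (B cell markers). They also stayed called without wild type 2 and knockout 3. Both fits used the preset correlation alone, without which none of the 5 held in the main fit. The RLE and upper-quartile factors left the median log2 fold change of all genes at -0.0016 and 0.0031, against 0.012 with TMM. Alox15 has no fold change in any setting, since its counts lay under the floor. Depth limits genes near 0.165 CPM over the 4 wild-type libraries.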

Other observations

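The tests with the mature neutrophil score, of pseudogenes and of gene calls in other splits were chosen after the result was seen, as were the single T lineage genes. With genotype and the mature neutrophil score in 1 edgeR fit of 13454 genes, 1347 rose and 144 fell with the score at an adjusted p under 0.05. The score was built from the same libraries, so its own members are not independent. Outside that list, genes that rose with it included the inflammasome sensor Nlrp3 (1.09 ± 0.09 log2 units per unit of score, SE), the lipid mediator receptor Ltb4r1 (1.14 ± 0.11) and arginase 2, Arg2 (1.25 ± 0.12). Genes that fell with it included the T cell receptor parts Cd3d (-0.47 ± 0.10) and Trbc2 (-0.64 ± 0.15), the T cell adaptor Lat (-0.39 ± 0.09), the mitotic kinase Cdk1 (-0.49 ± 0.11) and the cholesterol synthesis gene Sqle (-0.59 ± 0.14). The edgeR adjusted p of these genes was 3.63e-05 to 3.67e-05 for those that rose and 0.00605 to 0.0111 for those that fell. Several other falling genes had a smaller edgeR adjusted p and were not T lineage genes. Among them were the heat shock gene Hsph1 (-0.64 ± 0.08, adjusted p = 0.000143) and the predicted gene Gm10120 (-1.98 ± 0.27, adjusted p = 0.000171). The ribosomal protein pseudogene Rps16-ps2 (-0.70 ± 0.14, adjusted p = 0.00396) was another, and further pseudogenes fell too.

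T lineage transcripts were present in every library. Cd3d ran from 93.5 CPM in wild type 1 to 441 CPM in knockout 3, Cd3e from 70.2 to 137 CPM, Lck from 60.1 to 177 CPM and Gzma from 24.2 to 96.0 CPM over the 7 libraries. Cd28 ran from 65.4 to 239 CPM. Of other members of the same list, Cd8a reached at most 2.19 CPM, Gzmb 4.17 CPM and Klrb1c 0.972 CPM, and Ncr1 had 0 counts. Cd4 ran from 0 in wild type 1 to 39.9 CPM in knockout 3. T lymphocytes are not granulocytes, and the gate was not given in the sources used here.

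Processed pseudogenes and other pseudogenes made up 16 of the 154 genes at an unadjusted p under 0.05, or 10.4%, against 3.18% of the genes tested (Fisher's exact odds ratio 3.63, p = 3.16e-05). Among the 35 ways to split the 7 libraries into 4 and 3, 7 gave as high a share, the real one included, and the highest of the others was 14.4%. Gm12481, a processed pseudogene on chromosome 4 singled out after its values were seen, had 0 counts in the 3 knockouts and in wild type 1, and 194, 131 and 118 counts in wild types 2, 3 and 4.

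No gene passed in knockout against wild type, and all 35 splits gave at least that many, so the splits say nothing beyond the count of 0 itself. The highest of the others called 347 genes, for wild type 2, wild type 4 and knockout 3 against the rest, and another called 10, for wild type 1, knockout 1 and knockout 2; these are the 3 libraries with the lowest and the 3 with the highest mature neutrophil scores, a structure of the samples other than genotype. Whether neutrophil content hid genotype effects was examined with the mature neutrophil score as a covariate. That fit called 0 genes, with 448 at an unadjusted p under 0.05. The biological coefficient of variation was 0.483 in place of 0.563. Recovery of genotype effects with the covariate was simulated only at a lower dispersion (49 of 50 genes changed 8-fold). The count of 0 therefore does not decide the question, and effects that this fit could miss stay open. For the 5 lists called by camera, 29 of the 35 splits called as many, and the highest of the others called 20, so chance cannot be excluded.

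Knockout 1 shares Y-linked transcripts and the description stem with the 4 wild-type libraries, and whether it could be a wild-type library stays open. On 50 autosomal genes chosen without it, its position was 0.244, where wild type is 0 and knockouts 2 and 3 are 1. The left-out wild-type libraries lay at 0.297 to 0.951 and left-out knockouts 2 and 3 at -0.0694 and 0.0959 on axes made the same way, so the axis did not separate libraries it was not built from and the test cannot tell. Alox15 counts do not decide it, since wild type had 0. The sex-linked transcripts of knockout 1 were those of a male and those of knockouts 2 and 3 of females. Knockouts of both sexes would give these values, so they do not show that knockout 1 is wild type.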
